A study of Homo sapiens with 4 samples.

How the data were processed

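Each of 4 groups of THP-1 cells gave 2 libraries, counted on the nCounter human miRNA panel. The values used are raw counts per probe, which the authors deposited as 1 file per library and which carry no normalisation per the file headers. The panel held 654 human probes, 80 viral probes, 5 mRNA reference probes, 8 negative and 6 positive controls. The labels' protocols call the 2 libraries of a group biological replicates; nothing else in the sources used here says how the cultures were separated, so p-values measure the spread between these libraries. The libraries lay in lanes 5 to 12 of 1 cartridge, 2 neighbouring lanes per group.

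The authors also deposited a table of 673 probes with 1 signal value per group, whose processing is not given in the sources used here. Its human values equalled a weighted sum of the 2 libraries' counts, with a largest residual of 5.6e-06. The weights were 0.4523 and 0.4498 for untreated cells, 0.4857 and 0.5371 with Aa LPS and 0.5264 and 0.4699 with Pg LPS. With Pg(CSE) LPS they were 1.1128 and 0, so that column rests on replicate 1. The medians of its columns were 14.9, 18.0, 17.6 and 22.3. The origin of the group factors stays unknown, and the table was used as an alternative only.

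Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with TMM scaling over the tested probes, 1 mean per group and all 8 libraries in 1 fit with 4 residual degrees of freedom. P values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A human probe was tested if its count passed the mean plus 2 SD of the negative controls in at least 2 libraries, which left 234 of 654; that limit ran from 25.1 to 36.6 counts. Viral probes were kept out of the tests. This was settled after the files had been seen, and an alternative includes them. Fold changes are on the log2 scale with SE, and normalised counts are counts divided by the TMM scale. Exact permutation of 2 against 2 libraries cannot go below p = 0.333, so tests pool the spread across groups and probes. In a chi-square test of counts over tested probes, each pair of replicates differed by more than counting noise. Counting intervals would cover counting error only and were not used, because replicates varied beyond it.

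The design, the tests, 24 miRNA lists and the alternatives were fixed before the data were examined. So was the rule for named probes, which took up to 12 risers and 12 fallers with the largest change per comparison. Where fewer than 10 passed, the probes of smallest p filled the list to 10, given as values. The rule added 12 miRNAs linked to LPS or myeloid cells, of which hsa-miR-212 was not tested, with at most 8 counts. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as companions. Similarity was set beside 100 simulations of unchanged groups, in which edgeR called any probe in 2 to 6 of 100.

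The alternatives were DESeq2 1.42.0, limma 3.58.1, library size, upper quartile, the 100 most abundant probes, positive controls, mRNA reference probes, background subtraction, other filters, the compared groups alone, a replicate block, and each library left out. Of the added alternatives, chosen after seeing the data, 1 tested viral probes too, 1 left out the 18 probes that the files mark for background and 1 kept probes with a mean raw count of at least 100.

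The tests were tried on simulated counts of 654 probes, 200 of them changed in 1 group. There were 20 simulations for edgeR and limma and 3 for DESeq2. Of tested probes changed by 1 on the log2 scale, DESeq2 recovered 65.5% to 65.6% against untreated cells and limma 81.8% to 84.4%. For Pg LPS against untreated cells, edgeR recovered 85.8% of tested probes changed by 1 on the log2 scale and 98.9% of those changed by 1.5, with about 273 probes tested and 3.22% false calls. For Aa LPS it recovered 87.5% and 99.3% over 280 probes, and for Pg(CSE) LPS 85.7% and 99.1% over 269. All simulated probes shared 1 dispersion, and a change scaled the whole count, background included. These rates may therefore be better than those in the data. With all 9 tested let-7 members shifted by -1 with Pg(CSE) LPS, camera gave an unadjusted p under 0.05 in 20 of 20 simulations. That trial used 1 list without adjustment over lists. The let-7 median in the data was -0.27, so the trial does not show how often a shift of that size is found. miRNA genes were matched by name to a RefSeq table of the GRCh38.p14 assembly, used for which genes neighbour each other; 177 of 234 tested probes matched 1 gene. Figures were drawn with matplotlib 3.10.9.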

Results

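THP-1 cells, a human acute monocytic leukaemia line, were turned into macrophage-like cells with 50 ng/ml phorbol ester for 3 days. They were then left untreated or given 1000 ng/ml of bacterial lipopolysaccharide (LPS) for 4 hours. The LPS came from Aggregatibacter actinomycetemcomitans (Aa LPS), from Porphyromonas gingivalis (Pg LPS), or from P. gingivalis grown with cigarette smoke extract at 4000 ng/ml of nicotine equivalents (Pg(CSE) LPS). Both species are bacteria of periodontal disease. MicroRNA (miRNA) levels were counted with nCounter, a hybridisation assay that counts colour-coded probes without amplification, from 100 ng of total RNA. Each of the 4 groups held 2 libraries, which the labels call biological replicates.

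Human miRNA probes summed to 318141 and 290112 counts in the untreated libraries, 238810 and 272354 with Aa LPS, 215786 and 274771 with Pg LPS, and 217789 and 191301 with Pg(CSE) LPS. Spiked positive controls summed to 23589 counts in Pg(CSE) LPS replicate 2 and to 29144 to 33210 in the other libraries. The low total of that replicate therefore cannot be read as miRNA content alone. Of 654 human probes, 234 stood above background in at least 2 libraries and were tested. Within a group the libraries correlated at r = 0.988 to 0.992 across tested probes on the log2 scale, where probes are not independent replicates. They differed beyond counting noise, with chi-square values per degree of freedom of 7.0 with Pg(CSE) LPS to 53.5 with Aa LPS. The common dispersion corresponded to a coefficient of variation of 11.8% between replicates. Untreated, Aa, Pg and Pg(CSE) libraries lay in successive lanes of 1 cartridge, so lane order and group cannot be told apart.

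Aa LPS against untreated cells asked what the LPS of this species does to macrophage miRNAs. hsa-miR-29b, known to target transcripts of the extracellular matrix, fell from a normalised count of 460.5 ± 6.68 to 248.2 ± 65.2 (SD, n = 2), a log2 change of -0.89 ± 0.17 (SE, adjusted p = 0.0381 by edgeR). It was the 1 probe of 234 past the threshold in edgeR, and 37 probes had an unadjusted p under 0.05 where 11.7 were expected by chance. hsa-miR-146a, a feedback inhibitor of LPS signalling, had a log2 change of 0.51 ± 0.14 (adjusted p = 0.0937). hsa-miR-27a was at -0.61 ± 0.14 and hsa-miR-374a at -0.75 ± 0.17 (adjusted p = 0.0718 for both), hsa-miR-26b at -0.57 ± 0.14, hsa-miR-484 at -0.86 ± 0.22 and hsa-miR-32 at -0.79 ± 0.20. hsa-let-7f stood at -0.56 ± 0.16, hsa-miR-30c at -0.58 ± 0.16 and hsa-miR-485-3p at -0.55 ± 0.16. hsa-miR-155, an miRNA of inflammatory macrophages, was at -0.08 ± 0.17, hsa-miR-132 at 0.27 ± 0.14, hsa-miR-146b-5p at -0.13 ± 0.15, and the abundant hsa-miR-21 at -0.00 ± 0.11. hsa-miR-223, a myeloid miRNA, was at -0.06 ± 0.11, hsa-miR-142-3p at -0.10 ± 0.18, hsa-miR-9 at 0.08 ± 0.11 and hsa-let-7i at 0.00 ± 0.11. The 95% interval of the log2 change lay within 1 of 0 for 189 of the 234 probes. With a library left out, the number that fell was 0 without untreated replicate 1, 5 without untreated replicate 2, 0 without Aa LPS replicate 1, 3 without Pg LPS replicate 1, 9 (and 1 riser) without Pg LPS replicate 2, and 0 without Pg(CSE) LPS replicate 1 or 2. DESeq2 gave 0 risers and 3 fallers, limma 0 and 1, scaling on library size 1 and 4 and on the 100 most abundant probes 1 and 3, and these scalings moved the median of all probes from 0.00 to 0.11 and 0.12. Without a filter and with filterByExpr 8 probes fell, on positive controls 5, and with the compared groups alone or, chosen after seeing the data, without marked probes 4. The call of hsa-miR-29b was lost, with 0 probes left, on the upper quartile, on mRNA reference probes, after background subtraction, with probes above the limit in all libraries, with viral probes included and with a mean count of at least 100, the last 2 chosen after seeing the data.

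Pg LPS against untreated cells asked the same of the other species, and more probes passed. Of the tested probes, 40 fell and 6 rose against untreated cells. Among the 40 fallers, 11 had a mean raw count under 100. Without the marked probes, 33 of the 40 were still tested and below 0, and 32 kept their call. hsa-miR-30c dropped from 10000 ± 1289 to 4123 ± 842.9 normalised counts (SD, n = 2), a log2 change of -1.28 ± 0.16 (SE, adjusted p = 0.000217). hsa-let-7f, of the growth-restraining let-7 family, went from 4073 ± 901.9 to 1727 ± 108.0 (-1.24 ± 0.16) and hsa-miR-27a, transcribed with hsa-miR-23a, from 1671 ± 175.9 to 769.9 ± 127.3 (-1.12 ± 0.14). The largest fall was that of hsa-miR-484, at -1.53 ± 0.24, followed by hsa-miR-374a at -1.37 ± 0.18 and hsa-miR-197 at -1.35 ± 0.23. hsa-miR-582-5p (-1.18 ± 0.37), hsa-miR-26b (-1.17 ± 0.15), hsa-miR-18a (-1.06 ± 0.20) and hsa-miR-544 (-1.01 ± 0.18) also fell, and hsa-miR-574-3p and hsa-miR-509-3p fell to 0.498 and 0.499 of the untreated level. hsa-miR-18a belongs to the growth-promoting miR-17-92 cluster. Among the miRNAs fixed beforehand, hsa-miR-29b fell by 0.99 and hsa-miR-155 by 0.66 on the log2 scale (adjusted p = 0.0015 and 0.0214).

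The 6 probes that rose with Pg LPS were mostly dim. hsa-miR-517c+hsa-miR-519a rose by 0.93 ± 0.28, hsa-miR-566 by 0.93 ± 0.24, hsa-miR-193a-5p by 0.65 ± 0.19, hsa-miR-28-5p by 0.64 ± 0.18, hsa-miR-934 by 0.64 ± 0.19 and hsa-miR-526a+hsa-miR-518d-5p+hsa-miR-520c-5p by 0.58 ± 0.16. Of these, 5 had a mean raw count under 100, and negative control probes were 0.66 ± 0.14 higher on the same scale with Pg LPS. hsa-miR-146a (-0.13 ± 0.14), hsa-miR-132 (-0.02 ± 0.14), hsa-miR-146b-5p (-0.37 ± 0.16), hsa-miR-21 (0.25 ± 0.11), hsa-miR-9 (0.16 ± 0.11), hsa-miR-223 (-0.20 ± 0.11), hsa-miR-142-3p (0.25 ± 0.18) and hsa-let-7i (0.05 ± 0.11) did not pass. Risers and fallers numbered 14 and 33 with library-size scaling, 51 and 30 with scaling on the 100 most abundant probes, 58 and 21 with upper-quartile scaling, 2 and 39 on positive controls, and 0 and 2 with scaling on mRNA reference probes; scaling on abundant probes and on the upper quartile moved the median of all probes from 0.02 to 0.25 and 0.28. Leaving out a library gave 1 and 21 without untreated replicate 1, 0 and 18 without Pg LPS replicate 1, 2 and 35 without Pg(CSE) LPS replicate 1 and 2 and 31 without Pg(CSE) LPS replicate 2, DESeq2 gave 0 and 31, and background subtraction gave 14 and 30. They numbered 3 and 47 without a filter, 3 and 44 with filterByExpr, 17 and 33 with probes above the limit in all libraries, and 1 and 36 with the compared groups alone. The first 2 of these settings also moved the median of the 234 main probes, from 0.02 to -0.10 and -0.08.

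**Figure D1:**
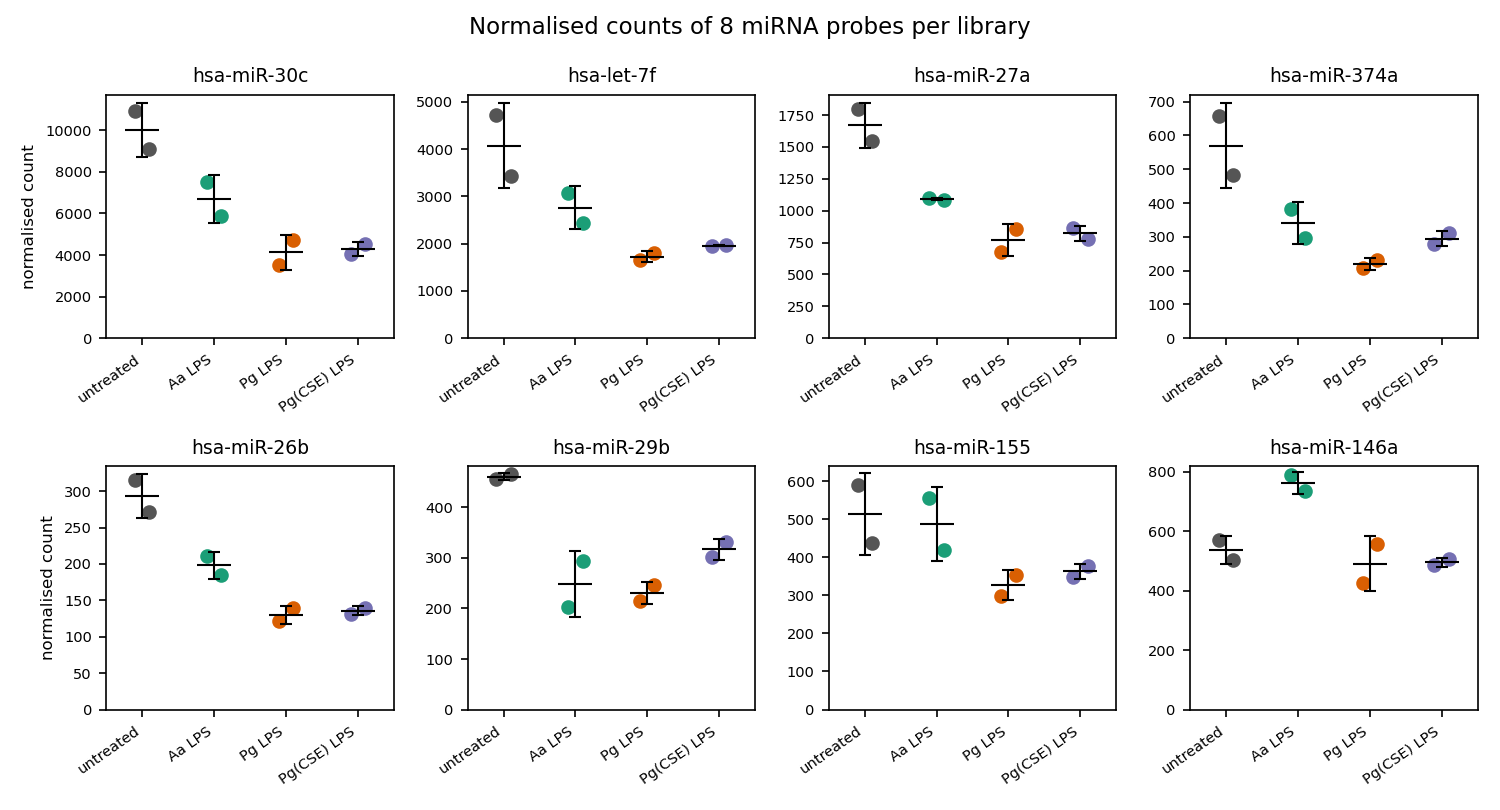
Normalised counts (vertical axes, from 0) of 8 probes in each of the 4 groups, with points for the 2 libraries and bars for the mean and SD. hsa-miR-30c goes from a mean of 10000 in untreated cells to 4123 with Pg LPS, while hsa-miR-146a has its highest mean, 761.5, with Aa LPS.

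Pg(CSE) LPS against untreated cells asked how the cells respond to LPS of the bacterium grown with smoke extract, and 31 of its fallers were among those of Pg LPS. In all, 36 probes fell and 30 rose. Of the fallers, 8 had a mean raw count under 100. Without the marked probes, 33 of the 36 were still tested and below 0, and all 33 kept their call. hsa-miR-30c fell to 4278 ± 347.4 (-1.23 ± 0.16, adjusted p = 0.000522), hsa-miR-27a to 821.4 ± 60.9 (-1.02 ± 0.14) and hsa-let-7f to 1960 ± 16.2 (-1.06 ± 0.16), each over n = 2. hsa-miR-484 (-1.33 ± 0.24), hsa-miR-1274b (-1.29 ± 0.33), hsa-miR-509-3p (-1.26 ± 0.28), hsa-miR-26b (-1.11 ± 0.15), hsa-miR-197 (-1.08 ± 0.23), hsa-miR-891a (-1.02 ± 0.33), hsa-miR-574-3p (-1.02 ± 0.18), hsa-miR-374a (-0.95 ± 0.18) and hsa-miR-20a+hsa-miR-20b (-0.95 ± 0.15) fell too. hsa-miR-1274b is an entry now regarded as a transfer RNA fragment. Of the miRNAs fixed beforehand, hsa-miR-29b (-0.54 ± 0.17) and hsa-miR-223, a myeloid miRNA, (-0.35 ± 0.11) fell, and hsa-miR-155 was at -0.50 ± 0.18 (adjusted p = 0.0503). hsa-miR-146a (-0.11 ± 0.14), hsa-miR-146b-5p (-0.20 ± 0.16), hsa-miR-132 (0.13 ± 0.14), hsa-miR-21 (0.14 ± 0.11), hsa-miR-9 (0.09 ± 0.11), hsa-miR-142-3p (0.05 ± 0.18) and hsa-let-7i (-0.03 ± 0.11) did not pass.

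The largest rises with Pg(CSE) LPS were those of hsa-miR-2114 (1.66 ± 0.32), hsa-miR-548l (1.19 ± 0.36), hsa-miR-200b, known from epithelial cells, (1.17 ± 0.28), hsa-miR-566 (1.17 ± 0.23), hsa-miR-1244 (1.17 ± 0.32) and hsa-miR-517c+hsa-miR-519a (1.08 ± 0.28). hsa-miR-769-5p, hsa-miR-652, hsa-miR-1266, hsa-miR-548b-3p, hsa-miR-324-3p and hsa-miR-145 rose by 1.06, 1.05, 1.00, 1.00, 0.97 and 0.96. Several of these lay near the background limit of 25.1 to 36.6 counts. hsa-miR-2114 and hsa-miR-652 had a mean raw count of 22.6 and hsa-miR-1244 one of 26.1. hsa-miR-548l, hsa-miR-769-5p, hsa-miR-200b and hsa-miR-1266 stood at 27.8, 27.9, 28.5 and 32.4. Among them only hsa-miR-2114 kept its call after background subtraction. Its log2 change went from 1.66 to 5.13 there, where counts below the mean of the negative controls were set to 0. That call therefore does not set its rise apart from background. Of the 30 risers, 23 had a mean raw count under 100, and the 80 viral probes of the panel lay 0.62 ± 0.06 higher on the same log2 scale with Pg(CSE) LPS. The brighter risers, named after their values were seen, included hsa-miR-191 (0.52 ± 0.16), hsa-miR-148b (0.39 ± 0.13) and hsa-miR-603 (0.79 ± 0.15), the last of which the files mark for background. Risers and fallers numbered 56 and 22 with library-size scaling, 73 and 21 on the 100 most abundant probes, 75 and 18 with the upper quartile, 6 and 53 on positive controls and 0 and 0 on mRNA reference probes; the first 4 moved the median of all probes from 0.09 to 0.27, 0.31, 0.33 and -0.17. They numbered 12 and 12 without untreated replicate 1, 10 and 26 without Pg(CSE) LPS replicate 1, 4 and 14 without Pg(CSE) LPS replicate 2, 7 and 33 with DESeq2, 13 and 29 after background subtraction, 13 and 73 without a filter, and 12 and 69 with filterByExpr. The last 2 settings also moved the median of the 234 main probes, from 0.09 to -0.23 and -0.22.

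**Figure D2:**
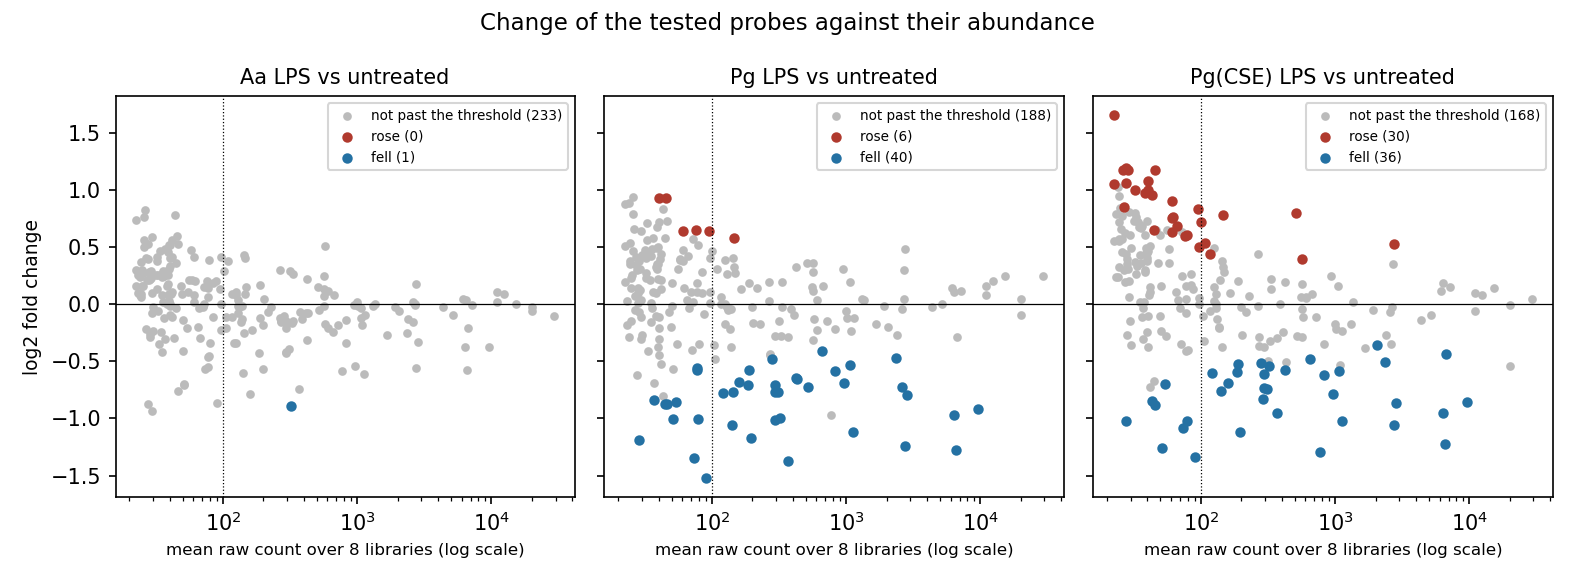
Log2 fold change against untreated cells (vertical axis) by mean raw count over the 8 libraries (horizontal axis, log scale) for the 234 tested probes, with a dotted line at a count of 100. With Pg(CSE) LPS, 23 of the 30 risers lie left of the line, while the fallers, 40 with Pg LPS and 36 with Pg(CSE) LPS, lie on both sides of it.

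Averaged over the 3 LPS groups, 39 probes fell and 20 rose against untreated cells. Of the fallers, 9 had a mean raw count under 100. Without the marked probes, 34 of the 39 were still tested and below 0. The falls were led by hsa-miR-484 (-1.24 ± 0.18), hsa-miR-30c (-1.03 ± 0.12), hsa-miR-374a (-1.02 ± 0.13), hsa-miR-509-3p (-0.99 ± 0.20), hsa-let-7f (-0.95 ± 0.12), hsa-miR-26b (-0.95 ± 0.11), hsa-miR-1274b (-0.95 ± 0.25) and hsa-miR-27a (-0.92 ± 0.11). hsa-miR-197 fell to 0.501 of the untreated level, hsa-miR-128, hsa-miR-891a and hsa-miR-574-3p fell by 0.84, 0.84 and 0.83, hsa-miR-29b by 0.81 and hsa-miR-155 by 0.41 (adjusted p = 0.0484). The risers with the largest change were hsa-miR-2114 (1.09 ± 0.28), hsa-miR-566 (0.90 ± 0.20), hsa-miR-1244 (0.89 ± 0.27), hsa-miR-145 (0.86 ± 0.24) and hsa-miR-525-3p (0.83 ± 0.28), and 15 of the 20 had a mean raw count under 100. hsa-miR-2114, hsa-miR-1244 and hsa-miR-525-3p had mean raw counts of 22.6, 26.1 and 25.9, near the background limit. The faller hsa-miR-891a, at 27.8, lay near it too. hsa-miR-146a was at 0.09 ± 0.12, hsa-miR-132 at 0.12 ± 0.11, hsa-miR-21 at 0.13 ± 0.09 and hsa-miR-223 at -0.20 ± 0.09. Risers and fallers numbered 28 and 27 with library-size scaling, 62 and 27 on the 100 most abundant probes, 63 and 23 with the upper quartile, 2 and 45 on positive controls, 0 and 8 on mRNA reference probes, 4 and 31 with DESeq2, and 1 and 15 without untreated replicate 1. Without Pg(CSE) LPS replicate 2 they were 6 and 31, without replicate 1 of that group 11 and 37, without untreated replicate 2 and without Aa LPS replicate 2 12 and 34 each, without Aa LPS replicate 1 10 and 38 and without Pg LPS replicate 1 11 and 36; the first 4 scalings named moved the median of all probes from 0.05 to 0.17, 0.24, 0.24 and -0.10.

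Aa LPS and Pg LPS, given at the same dose and time, differed at no probe past the threshold in edgeR. DESeq2 placed 10 probes higher with Aa LPS, scaling on library size 14 higher and 1 lower, and limma 0, and 39 probes had an unadjusted p under 0.05. The smallest p values belonged to hsa-miR-27b (0.57 ± 0.13 higher with Aa LPS), hsa-miR-146a (0.63 ± 0.14), hsa-miR-30c (0.70 ± 0.16) and hsa-let-7f (0.68 ± 0.16), each with an adjusted p of 0.0532. hsa-miR-26b (0.60 ± 0.15), hsa-miR-20a+hsa-miR-20b (0.59 ± 0.15), hsa-let-7a (0.54 ± 0.14), hsa-miR-320c (0.67 ± 0.18), hsa-miR-27a (0.50 ± 0.14) and hsa-miR-26a (0.47 ± 0.13) came next. The 40 probes that fell with Pg LPS had a median log2 change of -0.39 with Aa LPS against -0.79, but they were chosen on the Pg LPS libraries and both changes share the untreated libraries. In a test chosen after this was seen, fallers with Pg LPS were picked against 1 untreated library and Aa LPS was read against the other. Of 35 fallers picked against untreated replicate 1, 33 were below 0 with Aa LPS (median -0.27, other probes 0.04), and of 21 picked against replicate 2, 21 were (median -0.495, other probes 0.045). Lane drift was not separated from LPS by this test. Without a filter and with filterByExpr 6 probes passed, and without Pg LPS replicate 2, 1 probe did; scaling on the 100 most abundant probes gave 3 and moved the median of all probes from 0.02 to -0.09, and the upper quartile moved it to -0.15.

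Pg(CSE) LPS against Pg LPS asked whether growth with smoke extract alters the response to the LPS, and no probe was shown to differ. edgeR, DESeq2 and limma each called 0 probes, 21 had an unadjusted p under 0.05, and the 95% interval lay within 1 of 0 on the log2 scale for 196 of 234 probes. The smallest p values belonged to hsa-miR-769-5p (0.92 ± 0.28 higher with Pg(CSE) LPS), hsa-miR-651 (0.61 ± 0.20), hsa-miR-603 (0.43 ± 0.14), hsa-miR-27b (0.38 ± 0.13) and hsa-miR-200b (0.80 ± 0.27), all with an adjusted p of 0.444. hsa-miR-345 (0.74 ± 0.26), hsa-miR-208a (0.81 ± 0.29), hsa-miR-642 (0.78 ± 0.29), hsa-miR-2114 (0.78 ± 0.29) and hsa-miR-29b (0.45 ± 0.17) followed. Scaling on library size moved the median of all probes from 0.07 to 0.15 and positive controls to -0.11, again with 0 probes, and a miss of the threshold does not show that the responses were alike.

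Across all 4 groups, 49 probes differed in some way in a joint edgeR test. hsa-miR-30c, hsa-miR-27a and hsa-miR-26b had the smallest p (adjusted p = 0.000567 each), hsa-miR-29b had 0.00417 and hsa-miR-146a 0.0153, and 85 had an unadjusted p under 0.05. The count was 22 without untreated replicate 1, 29 without Pg(CSE) LPS replicate 1, 20 without Pg(CSE) LPS replicate 2, 22 after background subtraction and 1 with mRNA reference scaling.

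Grouped by the lists fixed beforehand, 4 of 5 tested members of the miR-30 family and 3 of 9 of the let-7 family fell with Pg(CSE) LPS (4 and 3 adjusted over the list alone). In the miR-30 family hsa-miR-30c fell by 1.23, hsa-miR-30b by 0.51, hsa-miR-30e by 0.44 and hsa-miR-30d by 0.52, while hsa-miR-30a was at 0.02 and below 0 with scaling on positive controls or mRNA reference probes. In the let-7 family, known to restrain growth, hsa-let-7f fell by 1.06, hsa-let-7a by 0.85 and hsa-miR-98 by 0.51. All 9 let-7 members were below 0, but 6 were with library-size scaling, where hsa-let-7d, hsa-let-7g and hsa-let-7i turned above 0, and 5 on the 100 most abundant probes or the upper quartile, where hsa-let-7e did so too. The medians were -0.51 and -0.27 for the miR-30 and let-7 families. camera gave each family an adjusted p of 0.0482, against an adjusted p of 0.593 for both with an estimated correlation; fry, which does not compare a list with other probes, gave 0.046 and 0.0322. With Pg LPS 3 of 5 miR-30 and 4 of 9 let-7 members fell (4 and 5 adjusted over the list alone), with camera adjusted p of 0.169 and 0.159. Both calls were lost on library size (adjusted p = 0.088) and on the 100 most abundant probes (0.101). No list passed without untreated replicate 2 or without Pg(CSE) LPS replicate 1, neither family did without untreated replicate 1, where LPS-lowered miRNAs passed with Aa LPS instead (1 list), the let-7 family alone did without Pg(CSE) LPS replicate 2, and 5 lists passed without Aa LPS replicate 2. Probes of one family may share signal, since their targets are close in sequence.

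No other list passed camera in the main setting. Fragments of other RNAs passed for Pg(CSE) LPS against Pg LPS on library size (adjusted p = 0.0387) and without Pg LPS replicate 1 (0.00428), against 0.126 in the main setting and 0.55 with an estimated correlation. Without Aa LPS replicate 2, myeloid and blood miRNAs passed for Pg(CSE) LPS against Pg LPS (0.0357), and the miR-29 family and LPS-lowered miRNAs with Aa LPS (0.0311 each). With Pg LPS the list of LPS-induced miRNAs had 0 risers and 2 fallers among 12 (2 adjusted over the list alone, adjusted p = 0.838), the fallers being hsa-miR-222 at -0.53 and hsa-miR-155 at -0.66. LPS-lowered miRNAs had 0 and 3 of 8 (1 riser and 4 fallers adjusted over the list alone, 0.484), and endotoxin tolerance and anti-inflammatory miRNAs 0 and 3 of 9 (3 adjusted over the list alone, 0.484). Macrophage differentiation miRNAs had 0 and 4 of 12 (4 adjusted over the list alone, 0.484), with a median of 0.03 against a downward direction in camera. miR-17-92 and paralogs had 4 fallers of 11 (4 adjusted over the list alone, 0.461) and the miR-23-27-24 clusters 2 of 5 (2 adjusted over the list alone, 0.43). The miR-99-125-let-7 clusters had 2 of 8 (2 adjusted over the list alone, 0.484), and myeloid and blood miRNAs 1 of 10 (1 adjusted over the list alone, 0.838), with a median of 0.03, a mean of -0.03 and an upward direction. The miR-29 family had 1 of 3 (1 adjusted over the list alone, 0.819), with a median of 0.11 against a downward direction, and the miR-15 and miR-16 family 0 of 7 (0 adjusted over the list alone, 0.484). Of the smoke-associated list, 4 of 10 members were tested, and 0 passed with Pg(CSE) LPS against untreated cells (0 adjusted over the list alone, 0.6) or against Pg LPS (0 adjusted over the list alone, 0.668).

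Log2 changes of the 3 LPS groups were set against one another. Across tested probes, which are not independent replicates, log2 changes against untreated cells correlated at r = 0.779 for Aa and Pg LPS, 0.771 for Aa and Pg(CSE) LPS and 0.884 for Pg and Pg(CSE) LPS (Spearman's rho 0.763, 0.770 and 0.876). Unchanged groups that shared the 2 untreated libraries gave mean r of 0.482, 0.481 and 0.480 in 100 simulations. The covariances were 0.1252, 0.1392 and 0.2461 against simulated 0.0266, 0.0274 and 0.0273, so the differences were 0.0987, 0.1118 and 0.2188. Pg and Pg(CSE) LPS shared 31 fallers and 6 risers, counts that the shared untreated libraries raise. With fallers of Pg LPS picked against 1 untreated library and Pg(CSE) LPS read against the other, a test also chosen after the values were seen, 35 of 35 were below 0 (median -0.67, other probes 0.14) and 20 of 21 (median -0.94, other probes 0.16). The simulations held no lane effect and drew each library independently. Drift along the lanes, away from the untreated libraries in lanes 5 and 6, could raise r and covariance too. It could also pass the test with split untreated libraries, so these values do not show a response common to the LPS groups. The correlation of Aa and Pg LPS ranged from 0.621 without Aa LPS replicate 2 to 0.836 without untreated replicate 2.

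**Figure D3:**
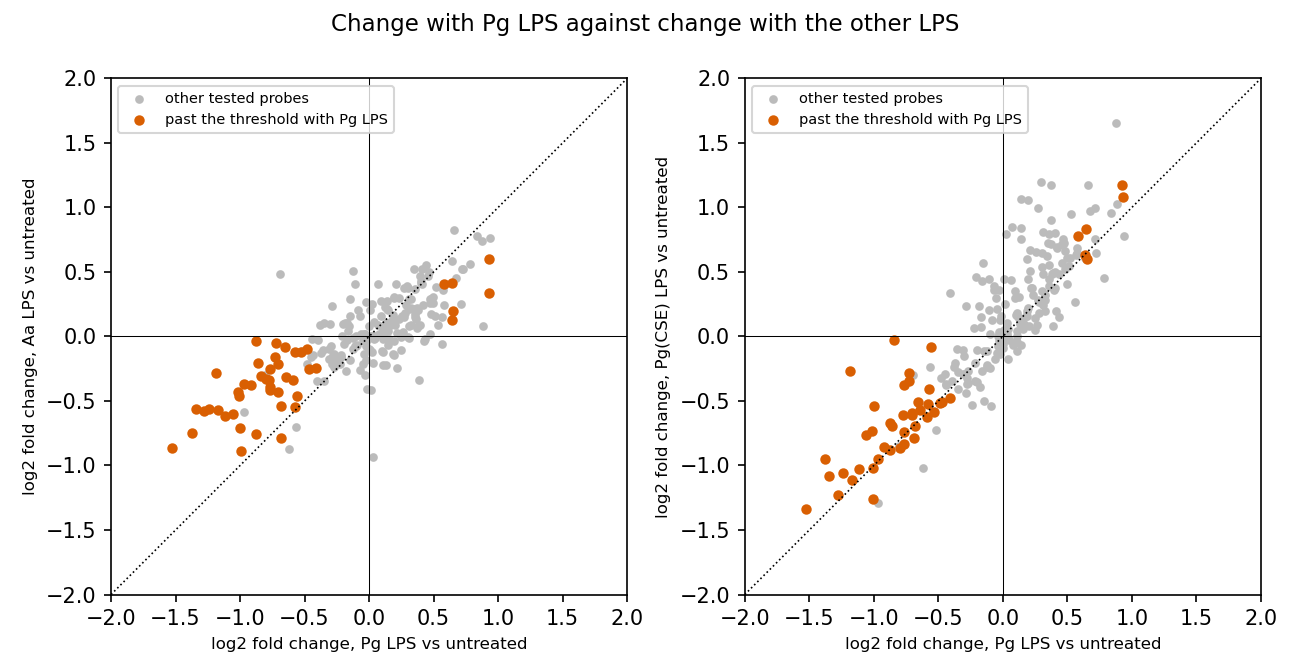
Log2 fold change against untreated cells with Pg LPS (horizontal axes) and with Aa LPS (left) or Pg(CSE) LPS (right), 1 point per tested probe, with the dotted line marking equal change. The 40 fallers with Pg LPS, at a median of -0.79, had medians of -0.68 with Pg(CSE) LPS and -0.39 with Aa LPS.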

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

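All tests in this part were chosen after the results they concern had been seen. Some probes for viral miRNAs, which take no part in the comparisons, passed when tested together with the human probes (edgeR). Of 80 such probes, 20 stood above background in at least 2 libraries, and of these 0 passed with Aa LPS, 2 rose with Pg LPS, 8 with Pg(CSE) LPS and 1 over all LPS groups, while 0 fell. kshv-miR-K12-6-5p, at -1.67 ± 0.60 (SE, adjusted p = 0.0531), and ebv-miR-BHRF1-1, at -0.35 ± 0.22, were the 2 below 0 with Pg(CSE) LPS. The Epstein-Barr virus probe ebv-miR-BART16, with raw counts of 300 to 602, rose by 0.85 ± 0.26 (SE) with Pg LPS, 0.85 ± 0.26 with Pg(CSE) LPS and 0.73 ± 0.22 over all LPS groups on the log2 scale. hsv1-miR-H8 rose by 0.97 ± 0.28 with Pg LPS and 1.09 ± 0.28 with Pg(CSE) LPS. With Pg(CSE) LPS ebv-miR-BART6-3p rose by 1.35 ± 0.36, hsv2-miR-H4-5p by 0.95 ± 0.30, ebv-miR-BART5 by 0.78 ± 0.26, hcmv-miR-UL112 by 0.78 ± 0.25, kshv-miR-K12-9 by 0.74 ± 0.20 and ebv-miR-BART6-5p by 0.53 ± 0.18. Negative controls were higher too, by 0.66 ± 0.14 with Pg LPS and 0.72 ± 0.14 with Pg(CSE) LPS. The rises of viral probes therefore do not show that a viral miRNA was present or rose.

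Of the 30 human probes that rose with Pg(CSE) LPS, 23 had a mean raw count under 100, and the viral probes and negative controls were higher on the same log2 scale, by 0.62 ± 0.06 and 0.72 ± 0.14 (SE). Background and a rise with LPS cannot be told apart for the 23 dim or the 7 brighter human risers. Of the 7 brighter risers 7 kept their call after background subtraction, but this moved their median change from 0.54 to 0.61 only, within a median SE of 0.15, and cannot remove background of a single probe; ebv-miR-BART16, with a mean raw count of 395.5, rose as well. Of the 23 dim ones 6 kept their call, while their median change went from 0.96 with a median SE of 0.25 to 1.21 with 0.47, so the other calls ended as the SE widened. A response to the LPS stays open, as does lane order.

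The 40 probes that fell with Pg LPS may owe their fall to the LPS, to TMM scaling or to drift along the lanes. Scaling on the spiked positive controls kept 36 of the 40 calls, with a median of -0.87 and a median SE of 0.235. That scaling also lowered the median of all probes, from 0.02 to -0.065, so it could hardly remove the falls. Other scalings raised that median, to 0.12 with library size, 0.25 with the 100 most abundant probes and 0.28 with the upper quartile. They kept 32 (median -0.70), 29 (-0.56) and 21 (-0.53) calls, and all 40 stayed below 0. These values argue against TMM scaling as the whole cause. The size of the fall and part of the calls depend on scaling. On mRNA reference probes 2 calls were left, because the median SE widened from 0.17 to 0.39 while the median change went from -0.79 to -0.88. Lane drift and LPS cannot be told apart: from the earlier to the later lane within a group the 40 probes changed by a mean of -0.044 ± 0.100 (SE over 4 pairs) relative to the other probes, and between groups by -0.153 per lane, which lies within 2 SE of that step. Medians taken per library gave 0.055 ± 0.109 against -0.178, more than 2 SE apart, so the answer turns on the summary used.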

How the results depend on the processing

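Alternatives with viral probes, without marked probes or with a minimum mean count were chosen after seeing the data. No named probe that had passed changed direction in any setting: of 3201 values of 134 named results, 2691 kept their side of the threshold or, in the authors' table, moved by less than 1 SE, 392 lost it, 114 gained it, 4 in the authors' table moved by more than 1 SE and 0 reversed. DESeq2 adjusted p given as NA stay out. Values of named results that passed in neither setting count as kept. Named risers lost their call more often than named fallers in some settings. On mRNA reference probes 30 of 30 risers and 27 of 37 fallers lost it, and 26 and 12 did without untreated replicate 1. Without a filter 24 risers and 0 fallers did, and on positive controls 22 and 0. With library size, the 100 most abundant probes and the upper quartile 0 risers and 1, 1 and 6 fallers did. In each of 12 alternatives fixed beforehand over full libraries, 12 probes fell with both Pg and Pg(CSE) LPS and 0 rose: hsa-let-7a, hsa-let-7f, hsa-miR-20a+hsa-miR-20b, hsa-miR-26a, hsa-miR-26b, hsa-miR-27a, hsa-miR-30c, hsa-miR-106a+hsa-miR-17, hsa-miR-197, hsa-miR-374a, hsa-miR-374b and hsa-miR-574-3p. This leaves out mRNA reference scaling, a choice made after its values were seen, and the 3 added alternatives; with a mean count of at least 100, hsa-miR-197 and hsa-miR-574-3p are not tested. The counts that moved by over 1.5 times follow, and the cause of these moves was not tested. Where other probes were tested, the scaling over the tested probes changed too. Without a filter and with filterByExpr, the median of the 234 main probes with Pg(CSE) LPS went from 0.09 to -0.23 and -0.22. DESeq2 gave 3 fallers with Aa LPS, 0 risers with Pg LPS, 7 with Pg(CSE) LPS, 4 with any LPS and 10 for Aa over Pg LPS. Library size gave 1 and 4 (rose and fell) with Aa LPS, 14 risers with Pg LPS, 56 and 22 with Pg(CSE) LPS, 14 and 1 for Aa over Pg LPS and 1 list shift, of fragments of other RNAs between Pg(CSE) and Pg LPS. The 100 most abundant probes gave 1 and 3, 51 risers, 73 and 21, 62 risers with any LPS, 3 for Aa over Pg LPS and 0 list shifts. Positive controls gave 5 fallers with Aa LPS and 2, 6 and 2 risers with Pg, Pg(CSE) and any LPS. mRNA reference probes gave 0 fallers with Aa LPS, 0 and 2 with Pg LPS, 0 and 0 with Pg(CSE) LPS, 0 and 8 with any LPS and 1 probe across the 4 groups. The upper quartile gave 0 fallers, 58 and 21, 75 and 18, and 63 and 23. Background subtraction gave 0 fallers with Aa LPS, 14, 13 and 9 risers with Pg, Pg(CSE) and any LPS and 22 across the groups. No filter gave 8 fallers with Aa LPS, 3 risers with Pg LPS, 13 and 73 with Pg(CSE) LPS, 6 risers with any LPS and 6 for Aa over Pg LPS, and filterByExpr 8, 3, 12 and 69, 6 and 6. Probes above the limit in all libraries gave 0 fallers with Aa LPS and 17 risers with Pg LPS. The compared groups alone gave 4 fallers with Aa LPS, 1 riser with Pg LPS and 19 with Pg(CSE) LPS. Viral probes included gave 0 fallers with Aa LPS. Without marked probes there were 4 fallers with Aa LPS and 11 risers with any LPS. A mean count of at least 100 gave 0 fallers with Aa LPS, 23 with Pg LPS, 11 and 19 with Pg(CSE) LPS, 9 risers with any LPS and 28 across the groups. The estimated correlation left 0 of 2 list shifts. Leaving out each library, where a lone library is assumed to vary like the others, gave 0 to 1 risers and 0 to 9 fallers with Aa LPS, 0 to 9 and 18 to 38 with Pg LPS, 4 to 26 and 12 to 43 with Pg(CSE) LPS, 1 to 15 and 15 to 44 with any LPS, 0 to 1 for Aa over Pg LPS, 20 to 45 across the groups and 0 to 5 list shifts, and r of 0.621 to 0.836, 0.634 to 0.820 and 0.790 to 0.905 for the 3 pairs of responses. With a replicate block, by the number in the file names, the counts were 8 and 37 with Pg LPS and 24 and 35 with Pg(CSE) LPS; same-numbered libraries deviated with correlations from -0.158 to 0.171, so the numbers do not pair the libraries, and the block moved no count by over 1.5 times. Dim probes limit the precision: 124 of the 234 had a mean raw count under 100.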

Other observations

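Tests in this part were chosen after the results had been seen, except the list tests and the first test of neighbouring genes, whose prediction was written first. The lists of other cell types, which in a clonal line do not measure cell composition, mostly held dim probes. With Pg(CSE) LPS hsa-miR-200b of the epithelial list rose by 1.17 ± 0.28 (SE), hsa-miR-206 of the muscle list by 0.54 ± 0.15 and hsa-miR-145 of the mesenchymal list by 0.96 ± 0.29, 1 of 3 tested members in each (1 adjusted over the list alone). hsa-miR-128 and hsa-miR-137 of the neuronal list fell by 0.88 ± 0.25 and 0.48 ± 0.13, 2 of 3 tested (2 adjusted over the list alone). None of these 4 lists passed camera (adjusted p from 0.36 to 0.447). Of 12 tested members of the chromosome 14 list 1 rose and 1 fell, of 5 on the chromosome 19 list 1 rose, and of 11 fragments of other RNAs 1 fell (the same numbers adjusted over the list alone), with camera adjusted p of 0.434, 0.38 and 0.36. The chromosome 19 list does not hold every probe of that cluster. Both hsa-miR-517c+hsa-miR-519a and hsa-miR-526a+hsa-miR-518d-5p+hsa-miR-520c-5p of the cluster rose, by 1.08 and 0.78. Liver, endothelial and erythroid lists had 1, 2 and 2 tested members and the embryonic list 0, too few for the list test.

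Some miRNAs of neighbouring genes changed unequally. Ratios of 2 probes within a library do not depend on scaling, and 7 of 12 such ratios between genes, among probes with a mean raw count of at least 100, changed over all LPS groups (limma), 1 with Aa LPS, 8 with Pg LPS and 6 with Pg(CSE) LPS. hsa-miR-23a over hsa-miR-27a rose by 1.02 ± 0.15 (SE) on the log2 scale (limma adjusted p = 1.88e-07), hsa-miR-25 over hsa-miR-93 by 0.69 ± 0.15, hsa-miR-191 over hsa-miR-425 by 0.64 ± 0.15 and hsa-miR-221 over hsa-miR-222 by 0.42 ± 0.15. Apart from these, arms of 1 hairpin changed unequally in 2 of 2 pairs over all LPS groups, with Pg LPS and with Pg(CSE) LPS. With Aa LPS they did in 0 of 2. Over all LPS groups hsa-miR-142-3p over hsa-miR-142-5p rose by 0.74 ± 0.15 and hsa-miR-423-3p over hsa-miR-423-5p fell by 0.39 ± 0.15 (limma adjusted p = 0.0233). limma pooled the spread of all 14 ratios into 1 value, as if the ratios were independent. All come from the same 8 libraries, and several share a probe. These p values are therefore smaller than 2 libraries per group can bear out, and the counts of changed ratios rest on them. Lane order is not separated from group here either.

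A shared primary transcript could make neighbouring miRNA genes change together. Among 74 probes in 28 clusters within 10000 bp, 8 of which held only the arms of 1 gene, the mean absolute difference in log2 change over all LPS groups was 0.457, where permuted probes of like abundance gave 0.447 (95% of permutations from 0.342 to 0.558; one-sided permutation p = 0.582, 10000 permutations). Over the 100 pairs of different genes in the other 20 clusters, a restriction chosen after that value was seen, it was 0.456 against 0.444 (0.321 to 0.579; permutation p = 0.586). Neighbouring genes were not shown to be closer to each other than random probes, and noise in dim probes widens all of these differences.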
